A study of Mus musculus with 12 samples.

How the data were processed

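The series holds 12 samples from mouse forelimb buds, 7 immunoprecipitated libraries and 5 input libraries. Per the labels, E11.5 samples came from the distal part of forelimbs of mixed C57BL/6 and CD1 background. They were profiled for H3K27ac and H3K27me3 in wild type and in Hoxa13-/-;Hoxd13-/- embryos, and for HOXA13 and HOXD13 in wild type. The E10.5 sample was profiled for H3K27me3 in CD1 forelimb buds with an antibody from another supplier. Per the labels' protocols, the Hoxa13 allele carries a neomycin cassette in its coding region and the Hoxd13 allele a lacZ reporter in its first exon. Chromatin was cross-linked with formaldehyde, and for HOXA13 with disuccinimidyl glutarate as well. Antibodies to HOXA13 and HOXD13 were made in-house, per the labels. Groups were taken from the sample titles, and each group holds 1 library. The labels give neither the sex of the embryos nor whether embryos were pooled.

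Each immunoprecipitated library has a peak list with 5 columns (chromosome, start, end, name and score). Reads were aligned with Bowtie 0.12.7 and peaks called with MACS 1.4 on mm9, per the submitters' processing notes. The names of the deposited lists pair each library with an input, so the authors called peaks per library. The deposited score is read here as the value the peak caller writes, -10 times the decimal logarithm of a p-value; its lowest value was 50, which is a p-value of 1e-05 on that scale, and many peaks share the score 3100 (4439 of 31933 in wild-type H3K27ac). This score depends on read depth and on the input, so it was used within 1 list, to rank, filter, match or describe peaks. The exception is the rank correlation of the scores of both factors across shared peaks, which does not compare their levels. Score differences are not read as amounts of a mark. The lists hold no read counts, and read depth is therefore unknown. Deeper libraries give longer lists, so a peak called in 1 genotype only can stand for a difference in depth or in enrichment as well as in the mark. The signal of the input libraries was not analysed here.

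The build was checked on the lists. Every list held peaks past the end of chromosome 1 of GRCm38 (195471971 bp), between 6 and 16 per list, so the peaks were treated as mm9. The reference genome and gene annotation at hand are of GRCm38. No gene, promoter or sequence was therefore assigned to a peak, coordinates were not converted, and the planned counts of promoters and of gene lists were not made. The RefSeq gene table of GRCm38 was used only for the chromosome of Hoxa13 and of Hoxd13. Coordinates are printed counting from 1.

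Overlap meant at least 1 bp in common. Shares carry Wilson 95% intervals, which cover the counting of peaks and not the spread between embryos. HOXA13 and HOXD13 peaks were merged into sites where they overlapped, and an H3K27ac or H3K27me3 peak was called bound where it overlapped a peak of either factor. The background of the factor overlap came from 100 random placements of the other factor's peaks on the same chromosomes. Shares of lost or gained peaks at bound peaks were set against 10000 random sets of unbound peaks, drawn with replacement with the same number in each of 25 bins (quintiles of score by quintiles of width within the list). The difference is the observed share minus the mean of the sets, its interval is the Wilson interval of the observed share minus that mean, and its place among the sets is a description of these libraries. Neither this interval nor the spread of the sets covers the counting error of the comparison peaks' own shares, so both are too narrow. The same procedure compared switches between marks, with peaks present in both genotypes as the matched sets. Clustering of lost or gained H3K27ac peaks was tested in windows of 1 Mb by permuting the lost or gained state among peaks of the same bin 1000 times and comparing each window's excess with the largest excess over all windows in each permutation. Medians of bound and unbound peaks were compared with bootstrap intervals from 1000 resamples.

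The matched comparison was tested on simulated data built on the 31933 wild-type H3K27ac peaks. With no difference put in, 20 simulations gave a mean of 0.168 percentage points (SD 0.518), and 3 of 20 lay outside the 2.5 to 97.5 percentiles of their sets. With 10 points put in, the mean was 10.2 (SD 0.463), and 20 of 20 lay above the 97.5 percentile.

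Before the data were examined, 7 alternatives were fixed: a score of 100 or more in every list, overlap of at least 50% of either peak, lists reduced to equal length by score, joining of peaks closer than 1000 bp, autosomes only, matching on score deciles alone, and binding by both factors in place of either. Counting peaks within 1000 bp as overlapping was added after seeing the data. Regions named in the text are the 3 peaks with the highest score in each of 6 classes, a rule also fixed beforehand; other regions are marked as chosen after their values were seen. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.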

Results

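HOXA13 and HOXD13 are homeodomain transcription factors of the distal limb bud, the part that forms the digits. Their binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the distal part of E11.5 mouse forelimb buds. H3K27ac, a histone mark of active promoters and enhancers, and H3K27me3, the mark laid down by Polycomb repressive complexes, were mapped in the same tissue of wild-type embryos and of embryos lacking both factors (Hoxa13-/-;Hoxd13-/-, called the double mutant here). H3K27me3 was also mapped in E10.5 forelimb buds of CD1 mice. Each of these 7 profiles came from 1 library, so no comparison has a replicate check, and p-values across libraries are not given. The lists held 31044 HOXA13 peaks and 22655 HOXD13 peaks. For H3K27ac there were 31933 wild-type peaks covering 59.8 Mb and 38115 double-mutant peaks covering 74.4 Mb. For H3K27me3 there were 28875 wild-type peaks covering 97.2 Mb, 19358 double-mutant peaks covering 60.9 Mb and 17556 E10.5 peaks covering 55.9 Mb. Read depth is unknown from the peak lists. All positions are on mm9, and intervals are Wilson 95% intervals that cover the counting of peaks only.

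The first question was whether HOXA13 and HOXD13 occupy the same places. Most did: 63.9% of HOXA13 peaks (63.4 to 64.4%) overlapped a HOXD13 peak, and 86.9% of HOXD13 peaks (86.5 to 87.3%) overlapped a HOXA13 peak. When the peaks of the other factor were placed at random on their chromosomes, these shares averaged 2.25% and 3.06% over 100 shuffles. The placement was uniform along each chromosome, so shares above it do not show that the factors bind together. Merging both lists gave 33743 sites, of which 19573 carried peaks of both factors, 11202 of HOXA13 only and 2968 of HOXD13 only. Sharing followed the authors' peak score. Of HOXA13 peaks in the lowest score decile 20.7% (19.3 to 22.2%) were shared, against 99.9% (99.7 to 100.0%) in the highest. For HOXD13 the corresponding shares were 61.6% (59.6 to 63.6%) and 99.7% (99.4 to 99.9%). Across the 19842 shared HOXA13 peaks, the scores of both factors had a Spearman rho of 0.748; this is across peaks, which are not independent replicates. The 3 shared peaks with the highest HOXA13 scores were on chromosome 9 at 59848960 to 59851298 (score 3211), on chromosome 10 at 29444036 to 29447335 (score 3203) and on chromosome 5 at 99797334 to 99798950 (score 3187). All 3 overlapped H3K27ac peaks in both genotypes. Another 68 HOXA13 peaks share the score 3100, so the order of the highest scores may not be one of binding strength. HOXA13 chromatin was cross-linked with an additional agent that was not used for HOXD13, so the longer HOXA13 list cannot be read as wider binding.

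**Figure D1:**
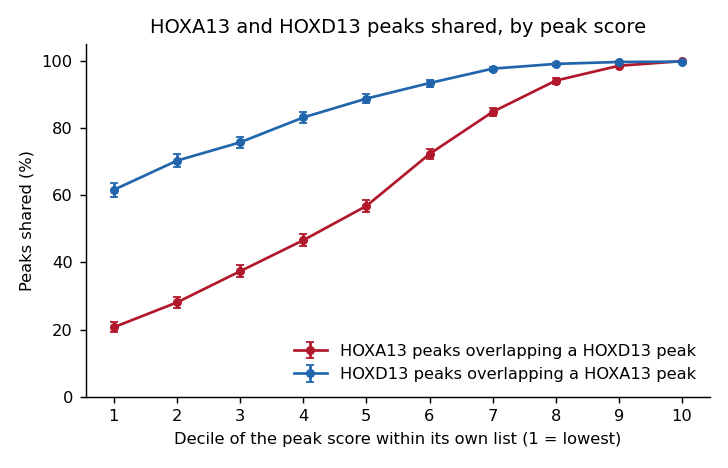
Share of HOXA13 peaks that overlap a HOXD13 peak (red) and of HOXD13 peaks that overlap a HOXA13 peak (blue), in percent, by decile of the peak's own score within its list. Points are shares with Wilson 95% intervals (1 library per factor); the HOXA13 share runs from 20.7% to 99.9% and the HOXD13 share from 61.6% to 99.7%.

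The next comparison asked how H3K27ac differed in the absence of both factors, and whether this depended on where they bind. A wild-type peak with no overlapping double-mutant peak is called lost here, and a double-mutant peak with no overlapping wild-type peak is called gained. Lost peaks numbered 4811 of 31933 and gained peaks 11464 of 38115. HOX13-bound peaks, which overlap a peak of either factor, made up 53.4% of lost peaks (52.0 to 54.8%) but 35.0% of wild-type peaks kept in the double mutant (34.4 to 35.6%). Among gained peaks 12.9% were bound (12.3 to 13.5%), against 36.1% of double-mutant peaks shared with wild type (35.5 to 36.6%). Loss was called at 21.3% of bound peaks (20.6 to 22.0%), and at 9.10% on average in random sets of unbound peaks matched on score and width. The difference was 12.2 percentage points (11.46 to 12.92), and the observed share lay above that of all 10000 sets. Gain was called at 13.3% of bound double-mutant peaks (12.7 to 14.0%) and at 27.5% of matched unbound peaks, a difference of -14.2 points (-14.8 to -13.5), with the observed share below that of all 10000 sets. These percentiles describe these libraries and not the genotypes in general. The intervals of the differences leave out the counting of the unbound peaks and are too narrow. Binding was mapped in wild type only, where HOX13 sites often lay in called H3K27ac. A lower gain at bound peaks was therefore partly set in advance by the definition of gained peaks. Both sets consisted mainly of peaks with low scores, with medians of 88.8 for lost and 87.0 for gained peaks, against 512 for kept and 538 for shared peaks. With both lists reduced to equal length by score, 6159 lost and 6846 gained peaks were called, so that lost peaks made up 47.4% of the peaks called in 1 genotype only, against 29.6% in the full lists.

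**Figure D2:**
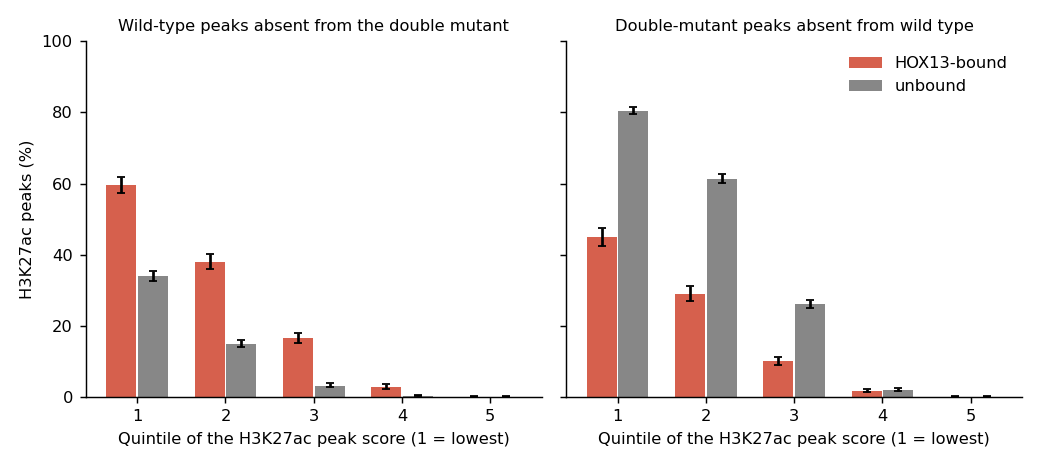
Share of H3K27ac peaks with no overlapping peak in the other genotype, in percent, by quintile of the H3K27ac peak score within its list, for wild-type peaks (left) and double-mutant peaks (right). Bars are shares with Wilson 95% intervals, for HOX13-bound (red) and unbound (grey) peaks; in the lowest quintile 59.7% of bound and 34.0% of unbound wild-type peaks were absent from the double mutant, while 44.9% of bound and 80.5% of unbound double-mutant peaks were absent from wild type.

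Loss of H3K27ac also differed between classes of binding and with how high the factor's peak scored. It was called at 23.9% of wild-type H3K27ac peaks bound by both factors (23.0 to 24.8%), at 17.8% of those bound by HOXA13 only (16.4 to 19.3%) and at 10.6% of those bound by HOXD13 only (8.98 to 12.6%). Matched unbound sets averaged 8.91%, 10.7% and 6.88%, in that order, and each observed share lay above all of its 10000 sets. From the lowest to the highest quintile of the HOXA13 score, the share of lost peaks went from 16.1% (14.6 to 17.7%) to 29.2% (27.3 to 31.1%). For the HOXD13 score it went from 16.8% (15.1 to 18.5%) to 28.0% (26.0 to 30.1%). Class and factor score went together. HOXA13 peaks without a HOXD13 peak had a median score of 75.2, against 201 for shared ones. For HOXD13 the medians were 69.6 and 156. The classes were not matched on factor score, so their difference in loss cannot be told apart from it. The 3 lost and bound peaks with the highest H3K27ac scores were on chromosome 11 at 88267419 to 88269822 (score 3100), on chromosome 2 at 106326327 to 106329098 (score 2454) and on chromosome 2 at 73789565 to 73793670 (score 1927). All 3 overlapped peaks of both factors. The 3 gained peaks with the highest scores were all on chromosome 2, at 74984036 to 74989106 (score 1838), at 154843981 to 154846808 (score 1443) and at 75243207 to 75249771 (score 1265). The first of these overlapped a HOXA13 peak (score 203) and a HOXD13 peak (score 82.6), the second a HOXA13 peak (score 94.7), and the last neither. Distance to promoters was not part of the matching, because gene models of the peaks' genome build were not used here.

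**Figure D3:**
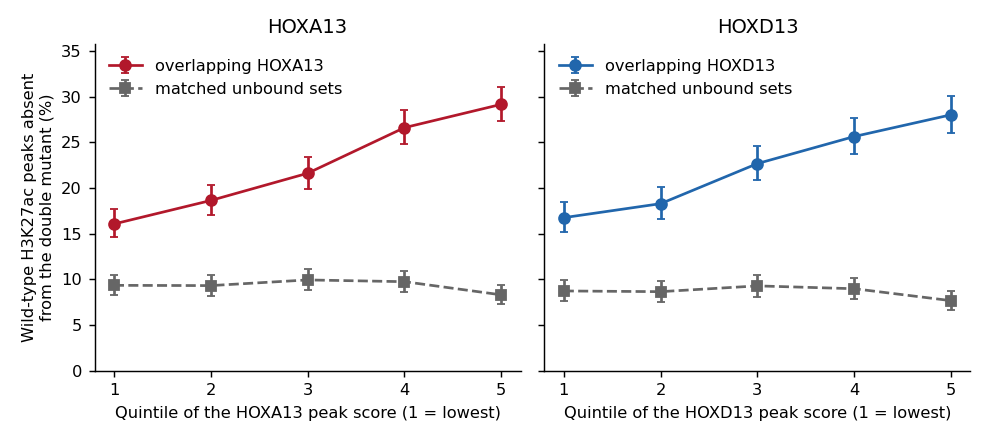
Share of wild-type H3K27ac peaks absent from the double mutant, in percent, by quintile of the score of the overlapping HOXA13 peak (left) or HOXD13 peak (right). Coloured points are observed shares with Wilson 95% intervals and grey squares are means of 10000 matched sets of unbound peaks with the central 95% of those sets; observed shares reach 29.2% and 28.0% in the highest quintiles, while the matched means stay between 7.67% and 9.94%.

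Seen from the binding sites, HOX13-bound sites often lay outside called H3K27ac and H3K27me3. Of the 33743 merged sites, 37.6% (37.1 to 38.1%) overlapped wild-type H3K27ac, 11.2% (10.82 to 11.49%) wild-type H3K27me3, 4.34% (4.13 to 4.56%) both marks and 55.6% (55.1 to 56.1%) neither. Neither mark was called in wild type at 49.2% of sites of both factors (48.5 to 49.9%), at 67.6% of sites of HOXA13 only (66.7 to 68.5%) and at 52.4% of sites of HOXD13 only (50.6 to 54.2%). In the double mutant these shares were 57.1% (56.4 to 57.8%), 68.3% (67.5 to 69.2%) and 54.3% (52.5 to 56.1%), in that order. Random placement of the sites gave 3.93% for wild-type H3K27ac, 4.73% for double-mutant H3K27ac and 4.12% for wild-type H3K27me3. In the double mutant, 34.3% of the same sites (33.8 to 34.8%) overlapped H3K27ac and 60.6% (60.1 to 61.1%) neither mark. At sites of both factors H3K27ac overlap was 43.7% (43.0 to 44.4%) in wild type and 37.6% (36.9 to 38.2%) in the double mutant. At sites of HOXA13 only it was 25.8% (25.0 to 26.6%) and 26.8% (26.0 to 27.6%), and at sites of HOXD13 only 41.7% (40.0 to 43.5%) and 41.1% (39.3 to 42.9%). These pairs of shares are of the same sites, and their difference was not tested. Peaks of HOXA13 only and of HOXD13 only had lower factor scores than shared peaks, so the contrast between classes is not one of binding by both factors alone. Among sites with H3K27ac alone in wild type, 8767 (78.2%) kept it alone in the double mutant, 2345 (20.9%) had neither mark there and 40 had H3K27me3 alone. Among sites with neither mark in wild type, 1193 (6.36%) had H3K27ac alone in the double mutant.

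H3K27me3 was compared between the genotypes next, and the X chromosome stood apart. Wild type had 9251 H3K27me3 peaks on the X, 32.0% of its list, covering 22.9 Mb. The double mutant had 385, covering 0.972 Mb. The ratio of wild-type to double-mutant peak numbers was 24.0 on the X, while it lay between 0.964 and 1.11 on every autosome. In covered length the ratio was 23.5 on the X and between 1.18 and 1.36 on the autosomes, with 74.3 Mb in wild type and 60.0 Mb in the double mutant over all autosomes. For H3K27ac the ratio was 1.05 on the X and between 0.792 and 0.914 on the autosomes. Of all wild-type H3K27me3 peaks 14952 had no double-mutant peak, 8984 of them on the X and 5968 on autosomes. In the opposite direction 3016 double-mutant peaks had no wild-type peak, 3007 of them on autosomes. Peaks called in wild type only were thus 83.2% of those called in 1 genotype only, and 66.5% on autosomes. On autosomes 30.4% of wild-type peaks (29.8 to 31.1%) were absent from the double mutant, and 15.8% of double-mutant peaks (15.3 to 16.4%) were absent from wild type. HOX13-bound autosomal wild-type peaks were absent from the double mutant in 21.8% of cases (20.4 to 23.3%), against 16.7% in matched unbound sets, above all 10000 sets. Without matching the direction was the opposite, since 32.1% of all 16404 unbound autosomal wild-type peaks were absent, so the excess at bound peaks holds only among peaks of like score and width. The matched difference was 5.12 points (3.73 to 6.58), and 8.14 points with a score of 100 or more in every list. Bound autosomal double-mutant peaks were absent from wild type in 8.27% of cases (7.27 to 9.39%), against 8.62% in matched sets, and the interval of the difference, -1.35 to 0.766 points, included 0. With equal list lengths the X ratio was 12.6, and 7017 peaks were called in wild type only and 4364 in the double mutant only, a wild-type share of 61.7%. Joining of neighbouring peaks gave 8998 and 2152, and a score of 100 or more in every list gave 10291 and 1186. The equal-length cut ranked peaks of all chromosomes together, so X peaks took places in the shortened wild-type list. Its counts are therefore no control for list length on autosomes.

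**Figure D4:**
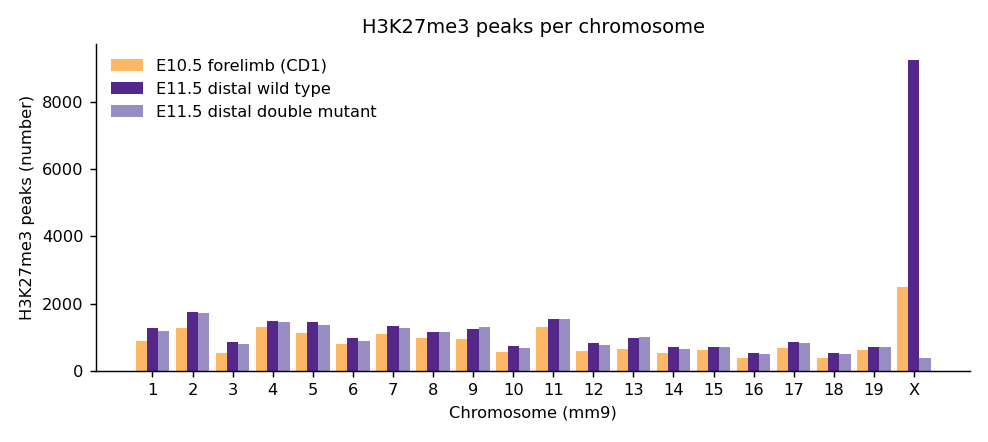
Number of called H3K27me3 peaks on each chromosome in E10.5 forelimb of CD1 mice (orange), E11.5 distal forelimb of wild type (dark purple) and of the double mutant (light purple), 1 library each. On the X the lists hold 2479, 9251 and 385 peaks, in that order.

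A further comparison asked whether loss of one mark went with gain of the other. Direct switches were rare. Of the 4811 lost H3K27ac peaks, 49 overlapped H3K27me3 in the double mutant but not in wild type, which is 1.02% (0.771 to 1.34%). Matched kept peaks gave 0.365%, and the difference of 0.654 percentage points (0.407 to 0.979) lay above all 10000 sets. It was 0.424 points with overlap of at least 50% of either peak. HOX13 bound 35 of these 49 peaks, or 71.4% (57.6 to 82.2%), against 53.4% of all lost H3K27ac peaks. The 3 with the highest H3K27ac scores were the chromosome 2 peak at 73789565 to 73793670, with a double-mutant H3K27me3 score of 90.0, another on chromosome 2 at 171457554 to 171461202 (H3K27ac score 1006) and 1 on chromosome 4 at 99125431 to 99127059 (H3K27ac score 436). The H3K27me3 peak at the first ran from 73793583 to 73794520. The peaks of both marks thus met only at an edge, short of 50% of either peak. The first was no longer in this class with a score of 100 or more in every list, and the other 2 were not when peaks within 1000 bp counted as overlapping. In the opposite direction, 328 of 11464 gained H3K27ac peaks overlapped H3K27me3 in wild type only, or 2.86% (2.57 to 3.18%), against 3.49% of matched shared peaks. This difference of -0.626 points had the opposite sign on autosomes alone (0.226 points) and with equal list lengths (0.0748 points), so no direction can be given. Of the 328, 36 were on the X. HOX13 bound 74 of the 328 peaks, or 22.6% (18.4 to 27.4%), against 12.9% of all gained H3K27ac peaks. The 3 with the highest H3K27ac scores were on chromosome 9 at 65022417 to 65024815 (score 761), on chromosome 8 at 92092985 to 92095757 (score 745) and on chromosome 12 at 57924176 to 57926379 (score 716). The last of these overlapped peaks of both factors, the chromosome 8 peak a HOXD13 peak and the chromosome 9 peak neither; the chromosome 8 peak left the class when peaks within 1000 bp counted as overlapping. More often H3K27me3 was called in both genotypes, at 5.14% of lost H3K27ac peaks (4.55 to 5.80%), against 13.6% of matched kept peaks, and at 12.6% of gained H3K27ac peaks (12.03 to 13.24%), against 9.89% of matched shared peaks.

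H3K27me3 of the E10.5 forelimb was set against E11.5 to see which earlier peaks were no longer called and whether these were still called in the double mutant. Of 17556 E10.5 peaks, 2257 or 12.9% (12.4 to 13.4%) had no E11.5 wild-type peak, and on autosomes 13.6% (13.1 to 14.2%). Of those 2257 peaks, 213 or 9.44% (8.30 to 10.7%) overlapped a double-mutant peak. The share was 15.1% (11.02 to 20.4%) for the 225 that overlapped a HOX13 peak and 8.81% (7.65 to 10.1%) for the other 2032. These groups were not matched on score or width, so the gap between them cannot be tied to binding. In the reverse direction, 19.5% of autosomal E10.5 peaks (18.9 to 20.1%) were absent from the double mutant, and 37.3% of these (35.5 to 39.0%) were called in wild type. On autosomes 79.1% of E10.5 peaks (78.4 to 79.7%) were called in all 3 lists. The 3 E10.5 peaks with the highest scores that were absent from wild type and called in the double mutant were on chromosome 7 at 81526722 to 81533789 (score 489), on chromosome 8 at 122933701 to 122938826 (score 371) and on chromosome 15 at 94636244 to 94638772 (score 337). Their double-mutant scores were 86.9, 116 and 52.9, so the first and the last were not in this class with a score of 100 or more, nor was the last when peaks within 1000 bp counted as overlapping. Stage cannot be told apart from antibody, strain and part of the limb, which also differ between the E10.5 and E11.5 libraries, and with a score of 100 or more in every list the absent share was 6.47%.

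Because several of the named peaks lay close together on chromosome 2, the stretch from 73 to 76 Mb was mapped in full; it was chosen after the values were seen. From 73 to 75 Mb, 34 of 82 wild-type H3K27ac peaks were lost and 14 of 70 double-mutant peaks were gained. From 75 to 76 Mb, 3 of 42 wild-type peaks were lost and 41 of 80 double-mutant peaks were gained. HOXA13 had 121 peaks in the first part and 69 in the second, and HOXD13 100 and 47. H3K27me3 peaks numbered 52 in wild type and 39 in the double mutant from 73 to 75 Mb, and 15 and 3 from 75 to 76 Mb. The stretch also holds the wild-type H3K27me3 peak from 74479846 to 74605456, which at 125611 bp was among the 3 widest of its list. Double-mutant H3K27me3 covered 96.3% of it in 5 peaks, and E10.5 H3K27me3 covered 61.2% in 18 peaks. Within it were 24 HOXA13 and 21 HOXD13 peaks, and H3K27ac covered 52.6% in wild type and 44.9% in the double mutant. The widest wild-type H3K27ac peak there ran from 74486156 to 74539552, and the widest double-mutant peak from 74506199 to 74554651. Hoxd13 maps to chromosome 2 and Hoxa13 to chromosome 6 in the RefSeq gene table, but gene positions on the genome build of the peaks were not used here, so none of these regions is assigned to a gene.

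**Figure D5:**
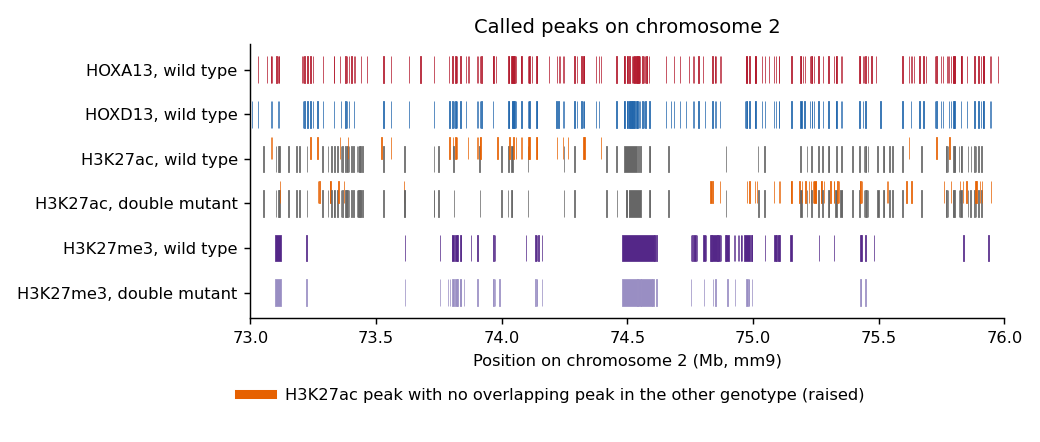
Called peaks from 73 to 76 Mb of chromosome 2 (mm9, horizontal axis in Mb), 1 row per list and 1 library per row; bars span each peak. Raised orange bars are H3K27ac peaks with no overlapping peak in the other genotype, 34 wild-type peaks from 73 to 75 Mb and 41 double-mutant peaks from 75 to 76 Mb among them.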

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

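The alternatives gave 85 values for the 13 results fixed beforehand. Of these, 48 stayed within the main interval or within 1.5 times the main count, 35 moved beyond that without a change of sign and 2 changed sign. With 1 library per group, the spread between embryos is unmeasured, and neither a paired analysis nor leaving out replicates was possible. Promoter counts, and alternatives that drop peaks near transcription start sites or change the promoter window, were not run for lack of mm9 gene models. Unknown read depth limits every count of peaks called in 1 genotype only. Where a value moved, the cause was not tested unless the setting itself shows it.

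With a score of 100 or more in every list, 66.2% of HOXA13 peaks overlapped HOXD13, 36.9% of bound sites overlapped wild-type H3K27ac, and 6883 H3K27ac and 1186 H3K27me3 peaks were called in the double mutant only. The H3K27ac loss difference was 14.0 points, the share of E10.5 H3K27me3 peaks absent from wild type 6.47% and the share of these called in the double mutant 7.56%. With overlap of at least 50% of either peak, the E10.5 share was 15.1% and the bound sites with H3K27ac 35.9%. With equal list lengths, 77.4% of HOXA13 and 77.2% of HOXD13 peaks were shared, 6846 H3K27ac peaks were gained and 7017 H3K27me3 peaks were called in wild type only. There, the H3K27ac loss and gain differences were 13.5 and -11.7 points, the E10.5 shares 19.3% and 13.3%, and 40.7% of bound sites overlapped H3K27ac. The H3K27me3 lists were cut over all chromosomes, with the many X peaks of wild type included. The 7017 peaks and the E10.5 shares are therefore no control for list length alone. With neighbouring peaks joined, the gain difference was -12.6 points and 8998 H3K27me3 peaks were called in wild type only. On autosomes alone, 5968 were, since the X peaks are left out, and the E10.5 share was 13.6%. Matching on score deciles alone gave a gain difference of -13.3 points. Binding by both factors gave loss and gain differences of 14.9 and -16.4 points, and 43.7% of sites with H3K27ac. With peaks within 1000 bp counted as overlapping, a setting chosen after seeing the data, 65.8% of HOXA13 and 87.9% of HOXD13 peaks were shared. The loss and gain differences were then 11.3 and -12.3 points, the E10.5 shares 10.1% and 11.2%, and 39.9% of bound sites overlapped H3K27ac.

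The H3K27me3 loss among gained minus shared H3K27ac peaks, -0.626 points in the full lists, was 0.226 points on autosomes and 0.0748 points with equal list lengths. It was -0.951 points with joined peaks and -0.181 points with peaks within 1000 bp counted. For equal lengths the cause was not tested. Results added after seeing the data gave 40 more values. Of these, 35 stayed within the main interval, within 1.5 times the main value or under a permutation p of 0.05, which allows change. The X ratio of H3K27me3 peaks does not use overlap, so the 50% and 1000 bp settings could not test it. Another 4 moved. For gained H3K27ac peaks from 75 to 76 Mb on chromosome 2, p exceeded 0.05 with a score of 100 or more. There it was 0.165 (23 gained, 15.5 given by score and width), against 0.006 (41 and 29.4). With equal list lengths the X ratio was 12.6 and the H3K27ac loss differences in the highest HOXA13 and HOXD13 score quintiles were 23.4 and 22.4 points. With a score of 100 or more, the H3K27me3 loss difference at bound autosomal peaks was 8.14 points. Of the 18 named entries (17 regions, 1 in 2 classes), 15 kept their class with a score of 100 or more and 14 with peaks within 1000 bp counted. All 18 did with equal lengths and joined peaks. With 50% overlap, 1 entry counted as kept (chromosome 2, 73789565 to 73793670) fell short for H3K27me3.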

Other observations

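The window tests, the X chromosome tests, the comparison of bound with unbound medians and the split by HOXD13 score were chosen only after the results were seen. The equal-length comparison of H3K27ac had been fixed before, but was chosen as a test of an explanation after its result was seen.

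H3K27me3 formed its widest wild-type peaks on chromosome 15 from 102725117 to 102906289 (181173 bp), on chromosome 2 from 74479846 to 74605456 (125611 bp) and on chromosome 11 from 96107103 to 96220059 (112957 bp). These were chosen by width after the values were seen. Double-mutant H3K27me3 covered 97.9%, 96.3% and 98.4% of them, in that order. H3K27ac overlapped them to different extents. On chromosome 15 it covered 4.03% in wild type and 16.5% in the double mutant, on chromosome 2 52.6% and 44.9%, and on chromosome 11 4.04% and 5.72%. HOXA13 had 18, 24 and 4 peaks within these domains, and HOXD13 18, 21 and 6. H3K27me3 at E10.5 covered 86.1%, 61.2% and 80.1% of them.

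Lost and gained H3K27ac peaks were unevenly placed along the genome. Lost peaks exceeded the number given by their scores and widths most in 3 windows of 1 Mb. In the window from 74 Mb on chromosome 2, 15 of 29 peaks were lost, where score and width gave 4.09, and HOX13 bound 10 of the 15. From 73 Mb on chromosome 2, 19 of 53 were lost, where 8.15 were given, and 14 were bound. From 47 Mb on the X, 15 of 18 were lost, where 4.28 were given, and 1 was bound. Most kept wild-type H3K27ac peaks in the window from 74 Mb on chromosome 2 also overlapped a HOX13 peak. The bound counts of lost peaks therefore do not tie the loss in these windows to binding. Gained peaks had their largest excess from 166 Mb on chromosome 2, where 52 of 103 were gained, 35.6 were given and 2 were bound. The next in excess were the windows from 56 Mb on chromosome 13 (40 of 81 gained, 27.3 given), from 80 Mb on chromosome 12 (34 of 73, 21.3 given) and from 78 Mb on chromosome 18 (30 of 51, 18.2 given). The window from 75 Mb on chromosome 2, beside those of lost peaks, came after these (41 of 80, 29.4 given, 12 bound). In all, 10 of 2184 windows of gained peaks and 3 of 2223 windows of lost peaks had a permutation p under 0.05.

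In the full lists, chance placement of lost peaks among peaks of like score and width is argued against for the 3 windows of lost peaks, each with a permutation p of 0.002 against the largest excess over 2223 windows. So is chance placement of gained peaks, whose lowest permutation p was 0.001, the smallest that 1000 permutations can give, though the window from 75 Mb on chromosome 2 went from a p of 0.006 (41 gained, 29.4 given) to 0.165 with a score of 100 or more (23 gained, 15.5 given), where it holds fewer peaks. The permutations treat peaks as independent; with neighbouring peaks joined, the p of the windows from 73, 74 and 75 Mb on chromosome 2 was 0.049, 0.035 and 0.043. No biological explanation was tested for these windows.

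Loss of H3K27ac at HOX13-bound peaks, with gain mostly elsewhere, was weighed against properties of the lists. Bound wild-type H3K27ac peaks were neither weaker nor narrower than unbound ones. Their median score was 108.7 higher (bootstrap 95% interval 87.3 to 131.8) and their median width 364 bp greater (335 to 392 bp). Wider peaks are more likely to overlap a HOX13 peak, so these medians describe the bound peaks and are no independent test. Against unbound sets matched on score and width, the loss difference was 12.2 points. With lists of equal length the gain difference was -11.7 points, which cannot decide whether a longer double-mutant list of weak peaks shaped the gain pattern. Of HOX13 sites mapped in wild type, 37.6% overlapped wild-type H3K27ac, against 3.93% with random placement. Bound double-mutant peaks are therefore less likely to be called gained at any list length. The loss of HOX13 binding itself may account for part of the H3K27ac loss: the excess over matched unbound peaks was 20.3 points in the highest HOXD13 score quintile and 7.98 points in the lowest. It stays open whether distance to promoters, which was not matched, or a lower number of the cells in which both factors bind contributes, and binding was mapped in wild type only.

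The excess of H3K27me3 peaks on the X in wild type was weighed in the same way. A lower sensitivity of the double-mutant library is argued against as the whole cause, since X peaks were absent from the double mutant 49.6 points more often than autosomal peaks of like score and width (97.2% against 47.5%). Loss of HOX13 binding at the X peaks themselves is argued against too, since 1.98% of the absent X peaks overlapped a HOX13 peak. A different share of female embryos may underlie it, since H3K27me3 covers the inactive X of female cells. The H3K27ac ratio on the X was 1.05, without an excess of like size, though above that of every autosome (0.792 to 0.914). In the X window from 47 Mb, 15 of 18 wild-type H3K27ac peaks were lost, 1 of them bound. Of E10.5 X peaks, 91.9% were called in wild type but 13.3% in the double mutant. Sex of the embryos and genotype cannot be told apart here, since the labels give no sex and each genotype has 1 library.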
